A study of Rattus norvegicus with 16 samples.

How the data were processed

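Transcripts were measured in islets of male Wistar rats with 16 Affymetrix Rat230_2 arrays. Per the labels, a preculture of 1 week used RPMI without serum, with 10 mmol/l glucose and BSA at 5 g/l. A culture of 18 h at 1 of 4 glucose concentrations (2, 5, 10 and 30 mmol/l) followed, with 1000 islets each. The deposited table holds signal intensity on a linear scale, which the authors made with GCOS, whose version and settings are not stated. In each array the mean after trimming 2% at each end was 149.994, so the authors' values carry a scaling of each array to 1 trimmed mean. The text files of the scanner software hold run information and were used to find which arrays shared a fluidics run, a scan day and a chip lot.

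The table has 31099 probe sets, of which 57 AFFX controls were used for array quality alone. Signals under 3.4, the 10th percentile of the table, were set to 3.4 and log2 was taken. Probe sets in the upper 60% of mean level (18625) were tested. Annotation by Entrez number gave 1 symbol to 20826 probe sets, several to 436 and none to 9780. A gene stands for its single-symbol probe set with the highest mean, which gives 14217 genes, 10223 of them tested. Genes without a single-symbol probe set were not analysed here.

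Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit over the 16 arrays and 12 residual degrees of freedom, eBayes with a mean-variance trend, two-sided tests and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. An adjusted p of a gene in the text is limma's. Contrasts were 5 over 2, 10 over 5, 10 over 2, 30 over 10 and 30 over 2 mmol/l, the mean of 2 and 30 over the mean of 5 and 10 mmol/l, and a moderated F-test over the 4 groups. Probe sets passing the F-test were sorted by the order of their 4 means. Where a value with the replicate block is given, the replicate number was a fixed term, with 9 residual degrees of freedom. The numbers of the labels were checked as pairs: after subtraction of group means, 24 pairs of arrays with the same number correlated at 0.136 to 0.434, the 72 other pairs at -0.264 to 0.130, and 16 of 16 arrays had their best match within their number. Each number was also 1 fluidics run, so preparation and run cannot be separated. The arrays were scanned on 3 days and came from 2 chip lots.

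Gene lists were tested with camera of limma, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists with at least 5 tested genes, and again with a correlation estimated from the data. The 22 pathway lists were glycolysis, pentose phosphate pathway and NADPH supply, fatty acid synthesis, cholesterol synthesis and uptake, fatty acid oxidation, tricarboxylic acid cycle and anaplerosis, oxidative phosphorylation, glucose-responsive carbohydrate response element genes, insulin granule and prohormone processing, exocytosis machinery, beta cell transcription factors, glucose sensing and stimulus-secretion coupling, ER chaperones and ER-associated degradation, integrated stress response and amino acid response, immediate early and calcium or cAMP responsive, oxidative stress and metallothionein, heat shock and cytosolic chaperones, hypoxia response, p53 targets and apoptosis, cell cycle, cytosolic ribosomal proteins and inflammation and NF-kB targets. The 9 lists of other cell types were alpha cell markers, delta cell markers, PP and epsilon cell markers, acinar cell markers, duct cell markers, endothelial cell markers, macrophage and leukocyte markers, stellate cell and fibroblast markers and Schwann and neural cell markers. They hold 680 genes, 597 with a single-symbol probe set and 489 tested. Tested members were counted as called over the probe sets tested and, beside that, adjusted over the list alone. These lists, the contrasts, the alternatives and the rule for naming genes were chosen before the data were examined.

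The rule names the 10 largest increases and 10 largest decreases among called genes whose groups do not overlap (10 over 2, 30 over 10, and ends over middle, there with both end means on 1 side of both middle means), 5 each way in the other contrasts, the 10 smallest F-test p, up to 4 members per list by smallest p, and a fixed set of well-known genes. The text prints a part of the genes the rule names. Ratios of 3 prime to 5 prime control probe sets and the mean of the hybridization controls were compared by exact permutation of 4 against 4 arrays. The comparison of the hybridization controls was chosen after seeing the data. Alternatives tried were the replicate block, preparation as a random block, scan day as a block, quantile normalization, median centring, no level filter and a stricter one, no floor, log2 of the value plus 50, eBayes without trend and robust eBayes, an adjusted p under 0.01, a 1.5-fold threshold, only the groups compared, the mean of a gene's probe sets, and leaving out each array and each replicate number. The replicate block together with an estimated correlation, and median centring for lists, were chosen after seeing the data.

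The analysis was tested on simulated data built from these arrays. For pairs of groups of 4 arrays, 14 to 18% of 1.3-fold and 40 to 58% of 1.5-fold changes were recovered. For 2-fold it was 74 to 82% and for 4-fold 92 to 100%, so changes under 1.5-fold are often missed. Between 5 and 15 unchanged probe sets were called per contrast. The data call more than the 200 changed here, so rates there can differ.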

Results

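The data are 16 whole-transcriptome oligonucleotide arrays of cultured rat pancreatic islets, the small endocrine organs that hold the insulin-producing beta cells. Islets from male Wistar rats were kept at 10 mmol/l glucose for 1 week and then for 18 h at 1 of 4 concentrations (2, 5, 10 and 30 mmol/l), with 4 arrays each. Per the labels the 4 experiments used different islet preparations, and a replicate number is taken here as 1 preparation with 1 array at each concentration. The number of arrays limits the precision. Values are signals in the scaled units of the deposited table, given as mean ± SD of 4 arrays. Changes between concentrations are log2 differences of group means ± SE, with n = 4 arrays per group.

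Across the 4 concentrations, the glucose-induced arrestin Txnip, which binds thioredoxin, had the smallest p of all named genes: its signal was 83.3 ± 9.23 at 2 mmol/l, 115 ± 19.5 at 5 mmol/l, 346 ± 90.0 at 10 mmol/l and 3882 ± 939 at 30 mmol/l (SD, n = 4). Plcxd3, a phospholipase-like gene, and the desaturase Scd2 also had higher means at each step, and Scd2 went from 1675 ± 226 at 2 mmol/l to 5277 ± 211 at 30 mmol/l. The clock-output transcription factor Dbp had lower means at each step, from 932 ± 231 at 2 mmol/l to 51.1 ± 14.2 at 30 mmol/l, as did its fellow clock gene Nr1d2 and the p53 target Phlda3. Btbd8, the cAMP regulator Crem and LOC100912041 had their lowest means at 5 or 10 mmol/l, with Btbd8 and Crem highest at 30 mmol/l. Tmem215 peaked at 10 mmol/l (3615 ± 402, 786 ± 138 at 2 mmol/l). By limma's moderated F-test, 7785 of 18625 probe sets (41.8%) changed at an adjusted p under 0.05, and 10276 did with the replicate block. Of the 7785, means rose at each step for 1002 (12.9%) and fell at each step for 1495 (19.2%). For 1998 (25.7%) means fell and then rose, for 2376 (30.5%) they rose and then fell, and 914 (11.7%) had another order. As the F-test used the same means, equally likely orders are no chance level here.

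**Figure D1:**
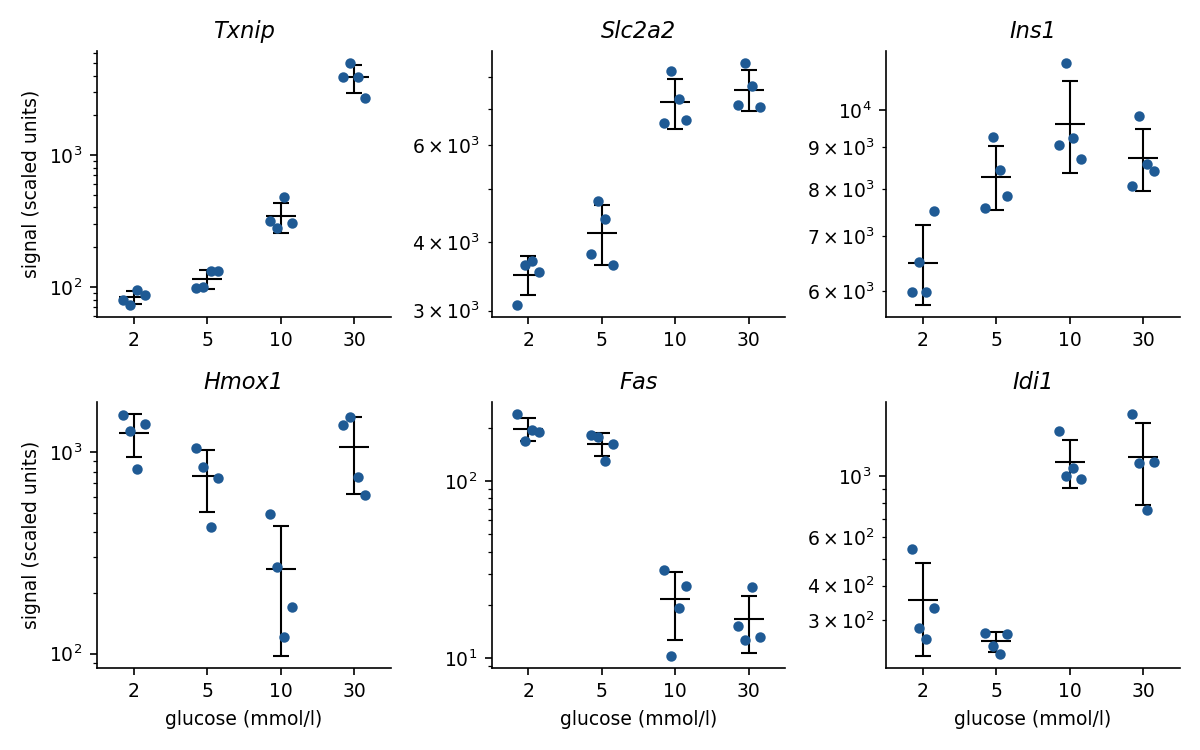
Signal of 6 genes on a log axis (scaled units) against glucose in mmol/l, with 1 point per array, 4 arrays per concentration, and bars for the mean ± SD. Txnip was highest at 30 mmol/l, Fas lower at 10 and 30 than at 2 and 5 mmol/l, and Hmox1 lowest at 10 mmol/l.

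From 2 to 5 mmol/l, the question is which transcripts differ between very low and near-basal glucose. The stress-responsive transcription factor Atf5 rose from 482 ± 65.7 to 919 ± 128 (SD, n = 4), which is 1.90-fold, Tmem80 rose 1.77-fold and Vmac, which codes for a vimentin-associated protein, rose 1.73-fold. LOC100911534 fell from 224 ± 65.0 to 104 ± 17.0, and the splicing factor Luc7l fell from 276 ± 37.4 to 137 ± 16.6. Ntrk2, a receptor of the neurotrophin BDNF, and Sigirr, a brake on interleukin receptors, were also among the 5 largest increases, with log2 changes of 0.84 ± 0.19 and 0.76 ± 0.18. Amdhd2, an enzyme of hexosamine breakdown, the clock repressor Nr1d1 and Bfsp1 were among the 5 largest decreases, with -1.25 ± 0.31 for Amdhd2, -0.96 ± 0.22 for Nr1d1 and -0.93 ± 0.21 for Bfsp1. Each of these 5 calls ended when any 1 of several arrays was left out, so no single array carried them. Ntrk2 lost its call without 4 of the arrays (highest adjusted p = 0.0732 without 5 mmol/l replicate 3). Sigirr lost its call without 7 of the arrays (highest adjusted p = 0.0948 without 2 mmol/l replicate 2). Amdhd2 lost its call without 7 of the arrays (highest adjusted p = 0.116 without 5 mmol/l replicate 1). Nr1d1 lost its call without 5 of the arrays (highest adjusted p = 0.0992 without 2 mmol/l replicate 2). Bfsp1 lost its call without 6 of the arrays (highest adjusted p = 0.105 without 2 mmol/l replicate 2). The call of Amdhd2 also ended with quantile normalization (adjusted p = 0.0554) and median centring (adjusted p = 0.0577).

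Ribosomal and secretory lists shifted up with the preset correlation alone. Among cytosolic ribosomal proteins, 3 of 20 members rose, 0 fell and 17 did not pass (15 and 0 adjusted over the list alone, 16 and 0 with the replicate block). Ribosomal proteins had adjusted p = 5.06e-11 by camera and adjusted p = 0.271 with an estimated correlation. Insulin granule and prohormone processing genes shifted up in the same way. Here 1 of 16 members rose, 0 fell and 15 did not pass (8 and 0 adjusted over the list alone, 9 and 0 with the replicate block). Insulin granule genes had adjusted p = 1.27e-06 by camera and adjusted p = 0.264 with an estimated correlation. The log2 change was 0.32 ± 0.07 for Scg5, a chaperone of prohormone convertase. For oxidative phosphorylation, 3 of 27 members rose, 0 fell and 24 did not pass (7 and 1 adjusted over the list alone, 9 and 0 with the replicate block). Log2 changes were 0.25 ± 0.05 for Cox8a and 0.35 ± 0.08 for Cox6c. Oxidative phosphorylation had adjusted p = 1.08e-05 by camera and adjusted p = 0.339 with an estimated correlation. In glycolysis 1 of 15 members rose, 0 fell and 14 did not pass (2 and 0 adjusted over the list alone, 5 and 0 with the replicate block). Glycolysis had adjusted p = 0.0109 by camera and adjusted p = 0.264 with an estimated correlation. The call of glycolysis was lost without 2 mmol/l replicate 3 (adjusted p = 0.0507) and with the mean of a gene's probe sets (median 0.06 against 0.15, adjusted p = 0.0617). In fatty acid oxidation 1 of 22 members rose, 0 fell and 21 did not pass (2 and 0 adjusted over the list alone, 5 and 0 with the replicate block). Fatty acid oxidation had adjusted p = 0.00782 by camera and adjusted p = 0.219 with an estimated correlation. The hypoxia response list also shifted up, with 0.40 ± 0.08 for Bnip3l, a mitophagy receptor, among its members. Here 3 of 23 members rose, 0 fell and 20 did not pass (3 and 0 adjusted over the list alone, 5 and 1 with the replicate block). Hypoxia response genes had adjusted p = 0.00782 by camera and adjusted p = 0.264 with an estimated correlation. The hypoxia call was lost with the mean of a gene's probe sets (median 0.08 against 0.15, adjusted p = 0.125). The integrated stress response and amino acid response list shifted down, with -0.58 ± 0.11 for Eif4ebp1 and -0.52 ± 0.11 for Psph, a translation repressor and a serine synthesis enzyme. Here 0 of 32 members rose, 3 fell and 29 did not pass (0 and 8 adjusted over the list alone, 0 and 8 with the replicate block). The stress response list had adjusted p = 0.00221 by camera and adjusted p = 0.430 with an estimated correlation. These list members rest on single arrays too. Scg5 lost its call without 5 of the arrays (highest adjusted p = 0.102 without 2 mmol/l replicate 2). Cox8a lost its call without 3 of the arrays (highest adjusted p = 0.0795 without 5 mmol/l replicate 1). Cox6c lost its call without 4 of the arrays (highest adjusted p = 0.0773 without 2 mmol/l replicate 2). Bnip3l lost its call without 3 of the arrays (highest adjusted p = 0.0773 without 2 mmol/l replicate 2). Eif4ebp1 lost its call without 1 of the arrays (highest adjusted p = 0.0517 without 2 mmol/l replicate 2). Psph lost its call without 3 of the arrays (highest adjusted p = 0.0667 without 2 mmol/l replicate 2). Quantile normalization ended 3 of these calls: Scg5 (0.09, adjusted p = 0.281), Cox8a (0.10, adjusted p = 0.491) and Cox6c (0.21, adjusted p = 0.168). Median centring ended those of Cox8a (adjusted p = 0.0828) and Bnip3l (adjusted p = 0.0540). With the replicate block, delta cell markers (adjusted p = 0.0346 against 0.202 without it) and stellate cell and fibroblast markers (adjusted p = 0.0274 against 0.620) passed as well, both upward, but with an estimated correlation too their adjusted p were 0.167 and 0.807. The 200 brightest probe sets rose by a median of 0.21 in this step, and with quantile normalization the calls of the ribosomal list (adjusted p = 0.382) and the insulin granule list (adjusted p = 0.143) ended. The 3 prime to 5 prime signal ratio of Actb, a sign of RNA quality, was lower at 2 mmol/l (1.76 ± 0.131) than at 5 mmol/l (2.04 ± 0.0835, SD, n = 4), higher at 5 mmol/l in 4 of 4 replicate numbers.

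In total, limma called 485 probe sets from 2 to 5 mmol/l, 310 higher and 175 lower, and 1839 with the replicate block, 1094 higher and 745 lower. Each array centred on its median gave 298, of which 229 were higher and 69 lower. The count was 104 without 2 mmol/l replicate 2, 246 without 2 mmol/l replicate 4, 157 without 5 mmol/l replicate 1, 256 without 5 mmol/l replicate 2, 184 without 5 mmol/l replicate 3 and 314 without 5 mmol/l replicate 4. For the tricarboxylic acid cycle list the median change (0.02) and the test pointed up and the mean (0.00) down at 0.868, and for the oxidative stress list the median (-0.01) and mean (-0.02) lay below 0 and the test pointed up at 0.620.

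From 5 to 10 mmol/l, lists of stress and p53 target genes shifted down and lists of lipid synthesis genes shifted up with the preset correlation, and not with an estimated one. The death receptor gene Fas fell from 163 ± 24.1 to 21.7 ± 9.13 (SD, n = 4), Phlda3, a p53 target that restrains Akt, fell from 462 ± 95.3 to 57.0 ± 16, and the metallothionein Mt2A fell from 1153 ± 509 to 139 ± 156. Gtse1, a p53-binding cell cycle gene, and the tight junction gene Tjp3 showed the largest decreases, from 119 ± 28.3 to 9.32 ± 8.49 and from 84.0 ± 11.7 to 7.0 ± 7.45, and these end near the floor of 3.4, where a fold is imprecise. Idi1, an enzyme of isoprenoid synthesis, rose from 251 ± 21.4 to 1134 ± 227, and Mfsd2a, a lysophospholipid transporter, rose from 22.6 ± 3.64 to 139.7 ± 26.8. Gem, a small GTPase that restrains calcium channels, rose 4.41-fold, the solute transporter Slc51a rose 4.42-fold and Bpifa2f, of a lipid-binding secreted family, rose 4.58-fold.

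The integrated stress response and amino acid response list shifted down. Here 0 of 32 members rose, 22 fell and 10 did not pass (0 and 24 adjusted over the list alone). Log2 changes were -2.0 ± 0.13 for Ppp1r15a, -2.06 ± 0.15 for Trib3, -1.45 ± 0.14 for Cebpb and -0.93 ± 0.09 for Sars1. The stress response list had adjusted p = 5.76e-11 by camera and adjusted p = 0.0563 with an estimated correlation. Its central transcription factor genes Ddit3 and Atf3 changed by -2.54 ± 0.28 and -1.68 ± 0.25. P53 targets and apoptosis genes shifted down too. Log2 changes were -1.37 ± 0.11 for Mdm2, -0.98 ± 0.19 for Cdkn1a and -0.88 ± 0.09 for Ccng1. These genes code for the ligase that degrades p53, a cell cycle inhibitor and a cyclin. Here 1 of 20 members rose, 9 fell and 10 did not pass (1 and 10 adjusted over the list alone, 2 and 11 with the replicate block). P53 targets had adjusted p = 0.00103 by camera and adjusted p = 0.0504 with an estimated correlation. In cholesterol synthesis and uptake 14 of 19 members rose, 1 fell and 4 did not pass (16 and 1 adjusted over the list alone). Log2 changes were 1.20 ± 0.14 for Sqle, 1.51 ± 0.18 for Hsd17b7 and 1.35 ± 0.16 for Dhcr7. Cholesterol synthesis had adjusted p = 7.32e-10 by camera and adjusted p = 0.0747 with an estimated correlation. In fatty acid synthesis 10 of 22 members rose, 1 fell and 11 did not pass (12 and 1 adjusted over the list alone). Log2 changes were 1.18 ± 0.08 for Scd2, 0.87 ± 0.11 for Fads1 and 0.73 ± 0.10 for Fasn. Fatty acid synthesis had adjusted p = 4.73e-05 by camera and adjusted p = 0.0563 with an estimated correlation. Targets of the carbohydrate response element shifted up with 1.57 ± 0.18 for Txnip, 1.47 ± 0.21 for Rgs16 and 0.38 ± 0.08 for Acly. Here 5 of 13 members rose, 1 fell and 7 did not pass (8 and 1 adjusted over the list alone, 8 and 1 with the replicate block). The carbohydrate response list had adjusted p = 2.21e-04 by camera and adjusted p = 0.0563 with an estimated correlation. Of the ER chaperones and ER-associated degradation genes 22 of 33 members rose, 3 fell and 8 did not pass (23 and 3 adjusted over the list alone). Edem2 (1.3 ± 0.11) and Pdia6 (0.47 ± 0.06) rose where Herpud1 (-0.51 ± 0.07) and Sel1l (-1.05 ± 0.14) fell. ER chaperones had adjusted p = 4.38e-09 by camera and adjusted p = 0.0642 with an estimated correlation.

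Secretory and beta cell lists shifted up with the preset correlation alone. For insulin granule and prohormone processing, 9 of 16 members rose, 0 fell and 7 did not pass (13 and 0 adjusted over the list alone, 15 and 0 with the replicate block). Log2 changes were 0.38 ± 0.07 for Scg3 and 0.60 ± 0.12 for Ptprn2, both granule proteins. Insulin granule genes had adjusted p = 1.68e-05 by camera and adjusted p = 0.163 with an estimated correlation. In the exocytosis machinery 3 of 15 members rose, 0 fell and 12 did not pass (3 and 0 adjusted over the list alone, 7 and 0 with the replicate block). Log2 changes were 0.66 ± 0.07 for Snap25, 1.0 ± 0.17 for Sytl4 and 0.47 ± 0.11 for Nsf, members of the membrane fusion apparatus. The exocytosis list had adjusted p = 0.0323 by camera and adjusted p = 0.0747 with an estimated correlation. Among beta cell transcription factors 5 of 11 members rose, 0 fell and 6 did not pass (6 and 0 adjusted over the list alone). Log2 changes were 0.84 ± 0.14 for Hnf4a, 0.61 ± 0.11 for Mafa and 0.59 ± 0.11 for Nkx2-2. The transcription factor list had adjusted p = 0.00346 by camera and adjusted p = 0.129 with an estimated correlation. The glucose transporter Slc2a2 rose from 4151 ± 519.9 to 7187 ± 745, and the calcium channel gene Cacna1c fell by 0.75 ± 0.12, while the glucose sensing list they belong to was not called (adjusted p = 0.291). The hybridization controls added to each array were brighter at 10 than at 5 mmol/l in 4 of 4 replicate numbers (10.1 ± 0.0767 against 9.84 ± 0.192 on the log2 scale, SD, n = 4), with an adjusted exact permutation p of 0.0857 (two-sided). Stellate cell and fibroblast markers passed upward with the replicate block (adjusted p = 0.00650) and not without it (adjusted p = 0.243) or with an estimated correlation beside the block (adjusted p = 0.429). For heat shock genes the median and mean (-0.08 and -0.01) lay below 0 and the test pointed up, and for delta cell markers the median (0.09) and the test pointed up and the mean (-0.15) down, with adjusted p of 0.990 and 0.935.

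By limma, 3935 probe sets changed from 5 to 10 mmol/l, 1867 higher and 2068 lower. With each array centred on its median, 1150 were higher and 2548 lower, so the balance of directions depends on the scaling. The largest shift of the median of all tested probe sets by this centring was -0.08 on the log2 scale, in this comparison. The call of the exocytosis list ended when the mean of a gene's probe sets was used (adjusted p = 0.0924).

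**Figure D2:**
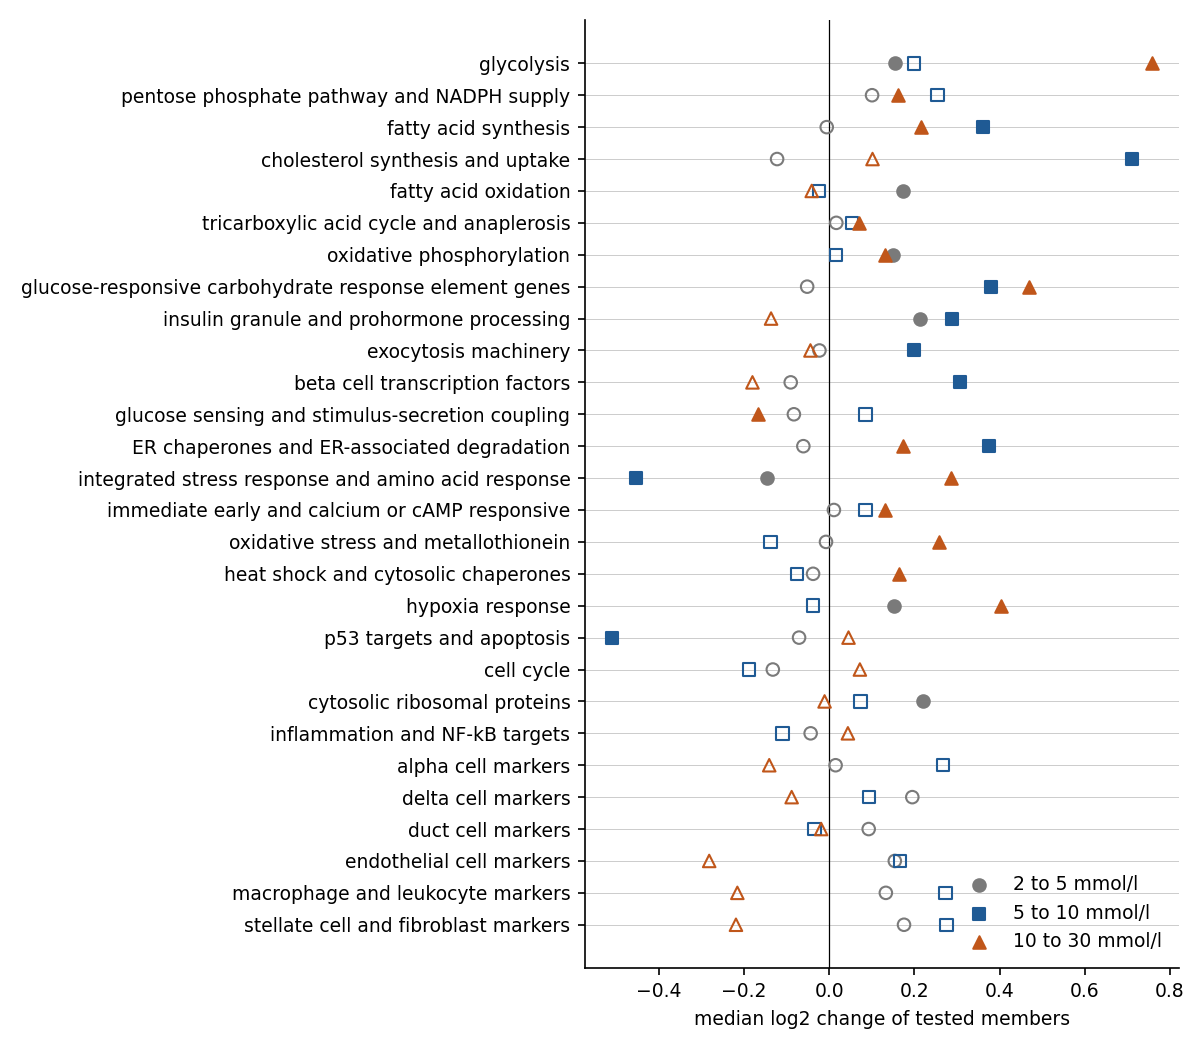
Median log2 change of each tested gene list (vertical axis: list; horizontal axis: median log2 change) in the steps from 2 to 5, 5 to 10 and 10 to 30 mmol/l, filled where camera gave an adjusted p under 0.05. Integrated stress response genes lie below 0 in the steps from 2 to 5 and 5 to 10 mmol/l and above 0 from 10 to 30 mmol/l.

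From 2 to 10 mmol/l, which contrasts low glucose with the concentration of the preculture, the receptor gene Adra2a, whose product restrains insulin release, rose from 168 ± 44.9 to 775 ± 62.4 (SD, n = 4). The largest increases were otherwise in Bpifa2f (10.5-fold), Tmem215 (4.63-fold), Gem (4.32-fold), Txnip (4.08-fold), Mfsd2a (4.07-fold), the RNA-modifying enzyme gene Tent5a (4.05-fold), Lrrc61 (3.85-fold), Ntrk2 (3.73-fold) and the immediate early gene Fos (3.55-fold). Dbp fell from 932 ± 231 to 102 ± 14, Mt2A from 1231 ± 316 to 139 ± 156 and Fas from 199 ± 30.0 to 21.7 ± 9.13. The other large decreases were in Gtse1, Tjp3 and Mybl1, a Myb-family gene, with -4.75 ± 0.48 for Gtse1, -4.17 ± 0.42 for Tjp3 and -3.09 ± 0.22 for Mybl1. Decreases in Phlda3, Spetex2l2, LOC100909675 and the ubiquitin ligase gene Rnf144b were -3.23 ± 0.20 for Phlda3, -3.32 ± 0.20 for Spetex2l2, -2.61 ± 0.37 for LOC100909675 and -2.59 ± 0.24 for Rnf144b.

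Islet hormone transcripts were among the brightest signals. Ins1 rose from 6498 ± 729 to 9607 ± 1231 with the deposited scaling, and log2 changes were 0.56 ± 0.09 for Ins1, 0.42 ± 0.12 for Ins2, 0.62 ± 0.09 for Iapp, 0.51 ± 0.10 for Gcg and 0.63 ± 0.06 for Sst. Quantile normalization forces the top ranks alike in all arrays and cannot test them. It ended calls of Ins1 (0.05), Ins2 (0.00), Iapp (0.02) and Gcg (-0.06), not Sst. The 200 brightest probe sets had a median change of 0.39 with the deposited scaling, and the hybridization controls were higher by 0.51 in 4 of 4 replicate numbers (adjusted exact p = 0.0571). The list of insulin granule and prohormone processing shifted up, with 0.57 ± 0.07 for Scg3, 0.59 ± 0.07 for Scg5 and 0.61 ± 0.08 for Pam. Here 15 of 16 members rose, 0 fell and 1 did not pass (15 and 0 adjusted over the list alone). Insulin granule genes had adjusted p = 2.83e-08 by camera and adjusted p = 0.129 with an estimated correlation. Cytosolic ribosomal proteins shifted up, with 0.52 ± 0.06 for Rps9. Here 16 of 20 members rose, 0 fell and 4 did not pass (16 and 0 adjusted over the list alone). Ribosomal proteins had adjusted p = 1.90e-06 by camera and adjusted p = 0.330 with an estimated correlation. With quantile normalization, limited as above, the test turned down (median change -0.04, adjusted p = 0.451). For oxidative phosphorylation 10 of 27 members rose, 1 fell and 16 did not pass (10 and 1 adjusted over the list alone, 12 and 4 with the replicate block). Log2 changes were 0.71 ± 0.11 for Ndufa1 and 0.53 ± 0.08 for Cox6c. Oxidative phosphorylation had adjusted p = 0.0248 by camera and adjusted p = 0.581 with an estimated correlation. This call ended with quantile normalization (adjusted p = 0.611), with median centring (adjusted p = 0.0577) and without 10 mmol/l replicate 4 (adjusted p = 0.0757) or 2 mmol/l replicate 2 (adjusted p = 0.0721).

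With the preset correlation alone, lists of stress and p53 target genes were lower at 10 than at 2 mmol/l and lipid synthesis lists higher. In the integrated stress response list 0 of 32 members rose, 24 fell and 8 did not pass (0 and 25 adjusted over the list alone). Log2 changes were -2.58 ± 0.28 for Ddit3, -2.33 ± 0.15 for Trib3 and -2.12 ± 0.13 for Ppp1r15a. The stress response list had adjusted p = 2.35e-11 by camera and adjusted p = 0.0888 with an estimated correlation. Among p53 targets and apoptosis genes 1 of 20 members rose, 11 fell and 8 did not pass (3 and 11 adjusted over the list alone, 2 and 11 with the replicate block). Log2 changes were -1.69 ± 0.11 for Mdm2 and -1.08 ± 0.19 for Cdkn1a. P53 targets had adjusted p = 0.00572 by camera and adjusted p = 0.0888 with an estimated correlation. In cholesterol synthesis and uptake 13 of 19 members rose, 1 fell and 5 did not pass (15 and 1 adjusted over the list alone). Log2 changes were 1.29 ± 0.14 for Sqle and 1.25 ± 0.14 for Lss. Cholesterol synthesis had adjusted p = 6.60e-07 by camera and adjusted p = 0.179 with an estimated correlation. In fatty acid synthesis 13 of 22 members rose, 2 fell and 7 did not pass (14 and 3 adjusted over the list alone). Log2 changes were 1.40 ± 0.08 for Scd2, 0.97 ± 0.11 for Fads1 and 0.75 ± 0.10 for Fasn. Fatty acid synthesis had adjusted p = 0.00145 by camera and adjusted p = 0.129 with an estimated correlation. Glycolysis shifted up, with 0.75 ± 0.10 for Tpi1 and 0.56 ± 0.07 for Pgam1. Here 6 of 15 members rose, 1 fell and 8 did not pass (8 and 1 adjusted over the list alone). Glycolysis had adjusted p = 0.00526 by camera and adjusted p = 0.129 with an estimated correlation. Carbohydrate response element targets followed, with 2.03 ± 0.18 for Txnip as the largest. Here 6 of 13 members rose, 1 fell and 6 did not pass (7 and 1 adjusted over the list alone). The carbohydrate response list had adjusted p = 0.00569 by camera and adjusted p = 0.129 with an estimated correlation. Among ER chaperones and ER-associated degradation genes 17 of 33 members rose, 3 fell and 13 did not pass (18 and 3 adjusted over the list alone). Log2 changes were 1.22 ± 0.11 for Edem2 and 0.61 ± 0.07 for Sec61b. ER chaperones had adjusted p = 6.36e-05 by camera and adjusted p = 0.179 with an estimated correlation. That call ended with quantile normalization (adjusted p = 0.195). Immediate early and calcium or cAMP responsive genes shifted up. Here 8 of 22 members rose, 2 fell and 12 did not pass (8 and 2 adjusted over the list alone). Crem (0.94 ± 0.10) rose but Myc (-2.15 ± 0.30) and Srf (-1.09 ± 0.17) fell. Immediate early genes had adjusted p = 0.0442 by camera and adjusted p = 0.330 with an estimated correlation. That call ended with the replicate block (adjusted p = 0.0507) and without 2 mmol/l replicate 1 (0.0671), 2 mmol/l replicate 3 (0.0926), 10 mmol/l replicate 1 (0.0607) or 10 mmol/l replicate 4 (0.0711), each as an adjusted p.

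The other pathway lists were not called from 2 to 10 mmol/l. In exocytosis machinery 5 of 15 rose and 0 fell (6 and 1 adjusted over the list alone, 6 and 1 with the replicate block) with adjusted p = 0.0944. In beta cell transcription factors 6 of 11 rose and 1 fell (6 and 1 adjusted over the list alone) with adjusted p = 0.0632. In glucose sensing 5 of 20 rose and 4 fell (5 and 4 adjusted over the list alone) with adjusted p = 0.370, a median of 0.02 and a mean of -0.02, and the test pointed up. Slc2a2 in that list rose from 3484 ± 282 to 7187 ± 745. In the pentose phosphate pathway 3 of 9 rose and 2 fell (3 and 2 adjusted over the list alone) with adjusted p = 0.496. In fatty acid oxidation 1 of 22 rose and 2 fell (1 and 2 adjusted over the list alone, 5 and 5 with the replicate block) with adjusted p = 0.667. In the tricarboxylic acid cycle 6 of 23 rose and 4 fell (6 and 4 adjusted over the list alone) with adjusted p = 0.512. In oxidative stress and metallothionein 5 of 24 rose and 8 fell (5 and 8 adjusted over the list alone) with adjusted p = 0.996. In heat shock 0 of 14 rose and 1 fell (0 and 0 adjusted over the list alone, 2 and 3 with the replicate block) with adjusted p = 0.827. In the hypoxia response 7 of 23 rose and 4 fell (8 and 4 adjusted over the list alone) with adjusted p = 0.181. In the cell cycle list 1 of 19 rose and 6 fell (1 and 7 adjusted over the list alone, 2 and 8 with the replicate block) with adjusted p = 0.272. In inflammation and NF-kB targets 1 of 16 rose and 4 fell (1 and 4 adjusted over the list alone, 2 and 6 with the replicate block) with adjusted p = 0.496.

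Of other cell types, alpha cell markers had a median change of 0.35 (adjusted p = 0.0944) and delta cell markers 0.36 (adjusted p = 0.496). Duct cell markers had -0.04 (adjusted p = 0.948), endothelial cell markers 0.32 (adjusted p = 0.519) and macrophage and leukocyte markers 0.14 (adjusted p = 0.370). Stellate cell and fibroblast markers had a median of 0.39 and were called with the replicate block (adjusted p = 5.91e-04), where 13 of 21 rose, and not without it (adjusted p = 0.0944) or with the block and an estimated correlation (adjusted p = 0.327). Lists with under 5 tested genes were not tested: the PP and epsilon cell markers had 3 with a median of 0.49, the Schwann and neural cell markers 3 with -0.60, and the acinar markers 1, the transcription factor gene Bhlha15, which rose by 0.78 ± 0.23 but lost its call without 2 mmol/l replicate 1 or 10 mmol/l replicate 3 (highest adjusted p = 0.0571). In total 6064 probe sets changed from 2 to 10 mmol/l by limma, 2910 higher and 3154 lower.

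From 10 to 30 mmol/l, the question is what high glucose adds to the preculture concentration. Txnip rose from 346 ± 90.0 to 3882 ± 939 (SD, n = 4), which is 11.2-fold, and Adm, the gene of the vasodilator peptide adrenomedullin, rose from 28 ± 8.59 to 283 ± 102. G0s2, an inhibitor of lipolysis, rose from 169 ± 62.7 to 1063 ± 291, the heme oxygenase gene Hmox1 rose from 264 ± 166 to 1058 ± 438, and Pfkfb3, an activator of glycolysis, rose 5.30-fold. Mt2A, the collagenase gene Mmp13, the kinase gene Matk, Btbd8 and Ccdc61 made up the other large increases, with 3.0 ± 0.66 for Mt2A, 2.72 ± 0.25 for Mmp13, 2.52 ± 0.30 for Matk, 2.21 ± 0.13 for Btbd8 and 2.03 ± 0.22 for Ccdc61. Among the largest decreases were those of Dcxr, a sugar reductase gene, from 71.3 ± 25.4 to 16.4 ± 12.9, Dhtkd1, of lysine breakdown, from 169 ± 18.5 to 46.2 ± 11.1, and Adhfe1, a mitochondrial transhydrogenase gene, from 105 ± 13.0 to 34.0 ± 9.30. Renbp, the kinetochore gene Kntc1, Cryl1, the transcription factor gene Klf15 and Lrrc39 fell as well, with -1.78 ± 0.36 for Renbp, -1.68 ± 0.32 for Kntc1, -1.62 ± 0.34 for Cryl1, -1.45 ± 0.20 for Klf15 and -1.27 ± 0.16 for Lrrc39. Npas3 and Atp6v1c2 had -1.68 ± 0.46 for Npas3 and -1.32 ± 0.38 for Atp6v1c2. Npas3 lost its call without 4 of the arrays (highest adjusted p = 0.0782 without 10 mmol/l replicate 2). Atp6v1c2 lost its call without 8 of the arrays (highest adjusted p = 0.138 without 10 mmol/l replicate 2). The call of Atp6v1c2 also ended with median centring (adjusted p = 0.0535).

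Glycolysis shifted up, with 1.32 ± 0.11 for Eno1, 1.19 ± 0.10 for Tpi1 and 1.16 ± 0.12 for Pfkp. Here 10 of 15 members rose, 0 fell and 5 did not pass (11 and 0 adjusted over the list alone). Glycolysis had adjusted p = 3.03e-12 by camera and adjusted p = 0.00238 with an estimated correlation. Carbohydrate response element targets shifted up with it, including 1.78 ± 0.13 for Klf10 and 1.67 ± 0.21 for Rgs16. Here 6 of 13 members rose, 0 fell and 7 did not pass (7 and 0 adjusted over the list alone). The carbohydrate response list had adjusted p = 2.10e-09 by camera and adjusted p = 0.00244 with an estimated correlation. In the hypoxia response 8 of 23 members rose, 0 fell and 15 did not pass (14 and 1 adjusted over the list alone, 13 and 1 with the replicate block). Log2 changes were 1.19 ± 0.14 for Pdk1 and 0.82 ± 0.10 for Pgk1. Hypoxia response genes had adjusted p = 2.70e-08 by camera and adjusted p = 0.00345 with an estimated correlation. No list of another cell type with at least 5 tested genes had a median above 0. In smaller lists, the acinar marker Bhlha15 had a change of 0.93 ± 0.23, the Schwann and neural cell markers a median of 0.29 and the PP and epsilon cell markers -0.17. Bhlha15 lost its call without 3 of the arrays (highest adjusted p = 0.0607 without 10 mmol/l replicate 2). The integrated stress response and amino acid response list shifted up, with 1.14 ± 0.12 for Phgdh, 0.71 ± 0.12 for Psat1 and 0.46 ± 0.07 for Nars1. Here 10 of 32 members rose, 0 fell and 22 did not pass (18 and 0 adjusted over the list alone, 18 and 0 with the replicate block). The stress response list had adjusted p = 1.87e-11 by camera and adjusted p = 0.0469 with an estimated correlation. Its transcription factor gene Ddit3 had a signal of 315 ± 199 at 10 mmol/l and 310.4 ± 119.9 at 30 mmol/l. Glycolysis, the carbohydrate response element, hypoxia and stress response lists are the 4 whose calls held with an estimated correlation.

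Other lists shifted with the preset correlation alone. For oxidative stress and metallothionein 7 of 24 members rose, 0 fell and 17 did not pass (8 and 1 adjusted over the list alone, 11 and 2 with the replicate block). Log2 changes were 1.01 ± 0.20 for Slc7a11 and 1.33 ± 0.29 for Srxn1, a cystine transporter and a peroxiredoxin repair enzyme. The oxidative stress list had adjusted p = 7.89e-06 by camera and adjusted p = 0.263 with an estimated correlation. Of the ER chaperones and ER-associated degradation genes 8 of 33 members rose, 0 fell and 25 did not pass (13 and 1 adjusted over the list alone, 15 and 1 with the replicate block). Log2 changes were 0.76 ± 0.12 for Creld2, 0.67 ± 0.14 for Pdia4 and 0.43 ± 0.08 for Dnajc3. ER chaperones had adjusted p = 1.03e-07 by camera and adjusted p = 0.102 with an estimated correlation. In the pentose phosphate pathway 2 of 9 members rose, 0 fell and 7 did not pass (2 and 0 adjusted over the list alone). Log2 changes were 0.76 ± 0.11 for Tkt and 0.84 ± 0.19 for Taldo1. The pentose phosphate list had adjusted p = 0.0135 by camera and adjusted p = 0.102 with an estimated correlation. For oxidative phosphorylation 2 of 27 members rose, 0 fell and 25 did not pass (2 and 0 adjusted over the list alone, 7 and 1 with the replicate block). The log2 change was 0.31 ± 0.06 for Atp5f1b. Oxidative phosphorylation had adjusted p = 0.00209 by camera and adjusted p = 0.455 with an estimated correlation. For the tricarboxylic acid cycle 3 of 23 members rose, 0 fell and 20 did not pass (4 and 0 adjusted over the list alone). The log2 change was 0.37 ± 0.08 for Pdhb. The tricarboxylic acid list had adjusted p = 0.0233 by camera and adjusted p = 0.293 with an estimated correlation. In fatty acid synthesis 0 of 22 members rose, 1 fell and 21 did not pass (3 and 1 adjusted over the list alone, 4 and 1 with the replicate block), where Fads1 fell by 0.48 ± 0.11. Fatty acid synthesis had adjusted p = 0.00533 by camera and adjusted p = 0.174 with an estimated correlation. The list shifted up (median 0.22), with 7 higher and 1 lower at an unadjusted p under 0.05 in limma. Immediate early and calcium or cAMP responsive genes shifted up with 0.97 ± 0.10 for Crem and 1.41 ± 0.30 for Myc. Here 5 of 22 members rose, 1 fell and 16 did not pass (5 and 1 adjusted over the list alone). Immediate early genes had adjusted p = 0.0284 by camera and adjusted p = 0.307 with an estimated correlation. Among heat shock genes and cytosolic chaperones 0 of 14 members rose, 0 fell and 14 did not pass (0 and 0 adjusted over the list alone, 5 and 0 at an unadjusted p under 0.05 in limma, 3 and 0 with the replicate block). Heat shock genes had adjusted p = 0.0251 by camera and adjusted p = 0.455 with an estimated correlation. Glucose sensing and stimulus-secretion coupling shifted down, with -0.37 ± 0.07 for Atp2a3, a calcium pump gene. Here 0 of 20 members rose, 1 fell and 19 did not pass (0 and 4 adjusted over the list alone, 0 and 6 with the replicate block). Glucose sensing had adjusted p = 0.0399 by camera and adjusted p = 0.297 with an estimated correlation. With quantile normalization the calls of oxidative phosphorylation (0.0896), the tricarboxylic acid cycle (0.149) and heat shock (0.149) ended. With the mean of a gene's probe sets so did those of the tricarboxylic acid cycle (0.0590) and glucose sensing (0.0985), and with median centring glucose sensing (0.0669), each given as an adjusted p. Leaving out 1 array ended 3 calls, again with the adjusted p. Glucose sensing lost its call without 10 mmol/l replicate 1 (0.0749), 10 mmol/l replicate 3 (0.0976) or 30 mmol/l replicate 2 (0.144). Heat shock lost its call without 10 mmol/l replicate 1 (0.0671) or replicate 2 (0.0564). Immediate early genes lost it without 10 mmol/l replicate 2 (0.0612), 10 mmol/l replicate 3 (0.0516), 30 mmol/l replicate 1 (0.0827) or 30 mmol/l replicate 4 (0.0608), or without the filter on level (0.148).

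Insulin granule genes, not called here (adjusted p = 0.131), passed downward with the replicate block (adjusted p = 0.0329) but not with an estimated correlation beside it (adjusted p = 0.412). The hybridization controls were lower at 30 than at 10 mmol/l by 0.24 in 4 of 4 replicate numbers (adjusted exact p = 0.0571). The exocytosis and duct cell lists had a test that pointed up with medians of -0.04 and -0.02 and means of -0.03 and 0.10 (adjusted p = 0.892 and 0.421). By limma 1271 probe sets changed from 10 to 30 mmol/l, 608 higher and 663 lower, and 2754 with the replicate block, 1230 higher and 1524 lower. With median centring the split was 557 higher and 398 lower. The count was 831 without 30 mmol/l replicate 2 and 804 without 30 mmol/l replicate 3.

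Between the extremes, 30 against 2 mmol/l, Txnip differed most and was 45.7-fold higher at 30 mmol/l. Bpifa2f, Btbd8, Mmp13 and Rgs16, a brake on G protein signalling, were the next largest increases, with 3.39 ± 0.48 for Bpifa2f, 3.14 ± 0.13 for Btbd8, 3.09 ± 0.25 for Mmp13 and 2.89 ± 0.21 for Rgs16. Dbp fell by 4.19 ± 0.19, and Gtse1, Phlda3, Fas and the DNA repair gene Rdm1 had changes of -4.04 ± 0.48 for Gtse1, -3.83 ± 0.20 for Phlda3, -3.63 ± 0.29 for Fas and -3.36 ± 0.50 for Rdm1. Slc2a2 was 3484 ± 282 at 2 mmol/l and 7588 ± 664 at 30 mmol/l (SD, n = 4), 2.18-fold higher.

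In glycolysis 12 of 15 members rose, 0 fell and 3 did not pass (13 and 0 adjusted over the list alone). Log2 changes were 1.94 ± 0.10 for Tpi1, 1.64 ± 0.11 for Eno1 and 1.0 ± 0.07 for Pgam1. Glycolysis had adjusted p = 3.06e-09 by camera and adjusted p = 0.00664 with an estimated correlation. Carbohydrate response element targets shifted up, with 1.93 ± 0.13 for Klf10 and 1.07 ± 0.10 for Fasn. Here 10 of 13 members rose, 0 fell and 3 did not pass (11 and 0 adjusted over the list alone). The carbohydrate response list had adjusted p = 1.65e-07 by camera and adjusted p = 0.00664 with an estimated correlation. For fatty acid synthesis 16 of 22 members rose, 2 fell and 4 did not pass (16 and 2 adjusted over the list alone). Log2 changes were 1.66 ± 0.08 for Scd2 and 0.70 ± 0.09 for Elovl5. Fatty acid synthesis had adjusted p = 7.50e-06 by camera and adjusted p = 0.0372 with an estimated correlation. For cholesterol synthesis 13 of 19 members rose, 0 fell and 6 did not pass (13 and 0 adjusted over the list alone, 15 and 1 with the replicate block). Log2 changes were 1.92 ± 0.16 for Dhcr7 and 1.44 ± 0.14 for Sqle. Cholesterol synthesis had adjusted p = 3.80e-07 by camera and adjusted p = 0.137 with an estimated correlation. In the hypoxia response 14 of 23 members rose, 1 fell and 8 did not pass (15 and 1 adjusted over the list alone). Log2 changes were 1.10 ± 0.12 for P4ha1 and 1.24 ± 0.14 for Pdk1. Hypoxia response genes had adjusted p = 1.16e-05 by camera and adjusted p = 0.0211 with an estimated correlation. With the replicate block and an estimated correlation, glycolysis was called (adjusted p = 0.0337) and the carbohydrate response (0.0516), hypoxia (0.0516) and fatty acid synthesis lists (0.0623) were not. ER chaperones and ER-associated degradation genes shifted up, with 1.44 ± 0.11 for Edem2 and 0.86 ± 0.08 for P4hb. Here 23 of 33 members rose, 2 fell and 8 did not pass (23 and 2 adjusted over the list alone). ER chaperones had adjusted p = 3.06e-09 by camera and adjusted p = 0.0578 with an estimated correlation. In immediate early and calcium or cAMP responsive genes 8 of 22 members rose, 2 fell and 12 did not pass (8 and 3 adjusted over the list alone, 10 and 5 with the replicate block). Log2 changes were 1.91 ± 0.10 for Crem and 2.41 ± 0.31 for Fos. Immediate early genes had adjusted p = 0.00620 by camera and adjusted p = 0.169 with an estimated correlation. Oxidative phosphorylation shifted up, with 0.53 ± 0.08 for Cox6c and 0.58 ± 0.09 for Cox5b. Here 14 of 27 members rose, 1 fell and 12 did not pass (15 and 1 adjusted over the list alone). Oxidative phosphorylation had adjusted p = 2.81e-05 by camera and adjusted p = 0.262 with an estimated correlation. For insulin granule genes 12 of 16 members rose, 1 fell and 3 did not pass (14 and 1 adjusted over the list alone). Log2 changes were 0.61 ± 0.07 for Scg3 and 0.54 ± 0.08 for Pam. Insulin granule genes had adjusted p = 4.27e-06 by camera and adjusted p = 0.137 with an estimated correlation. The 200 brightest probe sets had a median change of 0.32, and the hybridization controls were higher by 0.28 in 4 of 4 replicate numbers (adjusted exact p = 0.0571). For cytosolic ribosomal proteins 14 of 20 members rose, 0 fell and 6 did not pass (15 and 0 adjusted over the list alone). The log2 change was 0.52 ± 0.06 for Rps9. Ribosomal proteins had adjusted p = 5.38e-06 by camera and adjusted p = 0.311 with an estimated correlation. Quantile normalization turned this list's test downward (median -0.08, adjusted p = 0.521).

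In the pentose phosphate pathway 5 of 9 members rose, 1 fell and 3 did not pass (5 and 1 adjusted over the list alone). Log2 changes were 0.68 ± 0.11 for Tkt and 0.61 ± 0.13 for Pgd. The pentose phosphate list had adjusted p = 0.0272 by camera and adjusted p = 0.137 with an estimated correlation. Oxidative stress and metallothionein genes shifted up. Here 7 of 24 members rose, 4 fell and 13 did not pass (8 and 4 adjusted over the list alone, 14 and 5 with the replicate block). Log2 changes were 0.61 ± 0.07 for Prdx2 and 1.14 ± 0.16 for Glrx. The oxidative stress list had adjusted p = 0.0272 by camera and adjusted p = 0.568 with an estimated correlation. The integrated stress response list was lower, with -1.96 ± 0.15 for Trib3 and -2.50 ± 0.28 for Ddit3. Here 4 of 32 members rose, 18 fell and 10 did not pass (5 and 20 adjusted over the list alone). The stress response list had adjusted p = 0.00419 by camera and adjusted p = 0.316 with an estimated correlation. P53 targets and apoptosis genes were lower too, with -1.55 ± 0.11 for Mdm2, -1.05 ± 0.13 for Bbc3 and -1.19 ± 0.19 for Cdkn1a. Here 3 of 20 members rose, 8 fell and 9 did not pass (3 and 11 adjusted over the list alone). P53 targets had adjusted p = 0.0341 by camera and adjusted p = 0.108 with an estimated correlation. With quantile normalization the calls of insulin granule (0.0919), oxidative phosphorylation (0.133) and oxidative stress genes (0.0847) ended, and with the mean of a gene's probe sets that of the pentose phosphate pathway (0.0816), each given as an adjusted p. The oxidative stress call ended without 2 mmol/l replicate 3 (0.0644) or 30 mmol/l replicate 2 (0.0768) and the p53 call without 30 mmol/l replicate 4 (0.0512). The replicate block added the tricarboxylic acid cycle (adjusted p = 0.0405 against 0.0511) and stellate cell and fibroblast markers (adjusted p = 0.0405 against 0.251), both upward, and an estimated correlation ended both (adjusted p = 0.267 and 0.537). In fatty acid oxidation, heat shock and delta cell lists, which were not called, the median, mean and test differed in sign: the medians were -0.03, 0.05 and 0.07, the means -0.03, -0.04 and -0.12, and the tests pointed up. By limma, 6869 probe sets changed, 3031 higher and 3838 lower at 30 mmol/l.

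The series title names low, intermediate and high glucose, so the mean of 2 and 30 mmol/l was compared with the mean of 5 and 10 mmol/l. Hmox1 was 1251 ± 301 and 1058 ± 438 at 2 and 30 mmol/l against 764 ± 259.9 and 264 ± 166 at 5 and 10 mmol/l (SD, n = 4), a change of 1.43 ± 0.26. Adm, Matk, Itprid2 and the clock repressor Bhlhe40 were also higher at the ends, with 1.73 ± 0.20 for Adm, 1.43 ± 0.21 for Matk, 1.25 ± 0.11 for Itprid2 and 1.20 ± 0.16 for Bhlhe40. Of the other large increases, the arginine transporter Slc7a3, the Ras activator Rasgrf1 and the kinase Speg had 0.91 ± 0.22 for Slc7a3, 0.99 ± 0.21 for Rasgrf1 and 0.92 ± 0.23 for Speg. Genes lower at the ends included Dhtkd1, the activin receptor gene Acvr1c, the kinase gene Map2k6, Trappc6a and Tor4a, with -0.99 ± 0.10 for Dhtkd1, -0.84 ± 0.16 for Acvr1c, -0.72 ± 0.17 for Map2k6, -0.72 ± 0.10 for Trappc6a and -0.69 ± 0.16 for Tor4a. The calls of the increases of Bcl9l and Tm6sf2 and of 5 decreases depended on single arrays. Bcl9l lost its call without 9 of the arrays (highest adjusted p = 0.0772 without 5 mmol/l replicate 3). Tm6sf2 lost its call without 11 of the arrays (highest adjusted p = 0.0827 without 30 mmol/l replicate 2). Kntc1 lost its call without 4 of the arrays (highest adjusted p = 0.0554 without 5 mmol/l replicate 2). Defb1 lost its call without 9 of the arrays (highest adjusted p = 0.0691 without 5 mmol/l replicate 3). Insrr lost its call without 4 of the arrays (highest adjusted p = 0.0605 without 5 mmol/l replicate 2). Ccdc113 lost its call without 11 of the arrays (highest adjusted p = 0.0779 without 10 mmol/l replicate 3). Mzf1 lost its call without 14 of the arrays (highest adjusted p = 0.0961 without 2 mmol/l replicate 2). Quantile normalization ended the calls of Ccdc113 (adjusted p = 0.0511) and Mzf1 (adjusted p = 0.0513). Median centring ended those of Bcl9l (0.0537), Ccdc113 (0.0570) and Mzf1 (0.0611), each as an adjusted p.

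Carbohydrate response element targets had a higher mean over 2 and 30 than over 5 and 10 mmol/l, with 1.52 ± 0.13 for Txnip, 0.92 ± 0.09 for Klf10 and 0.96 ± 0.15 for Rgs16. Here 6 of 13 members rose, 0 fell and 7 did not pass (7 and 0 adjusted over the list alone). The carbohydrate response list had adjusted p = 1.18e-06 by camera and adjusted p = 0.0198 with an estimated correlation. This call ended with the replicate block and an estimated correlation (adjusted p = 0.104). Txnip was lowest at 2 mmol/l, so the call does not stand for high values at 2 mmol/l. In glycolysis 8 of 15 members rose, 1 fell and 6 did not pass (9 and 1 adjusted over the list alone, 10 and 2 with the replicate block). Log2 changes were 0.62 ± 0.08 for Eno1 and 0.58 ± 0.09 for Pfkp. Glycolysis had adjusted p = 3.0e-05 by camera and adjusted p = 0.0526 with an estimated correlation. The integrated stress response list was higher, with 0.79 ± 0.08 for Phgdh, 0.61 ± 0.08 for Psph and 0.60 ± 0.08 for Eif4ebp1. Here 11 of 32 members rose, 0 fell and 21 did not pass (15 and 0 adjusted over the list alone). The stress response list had adjusted p = 2.09e-10 by camera and adjusted p = 0.0769 with an estimated correlation. Among ER chaperones 8 of 33 members rose, 1 fell and 24 did not pass (10 and 1 adjusted over the list alone). Log2 changes were 0.65 ± 0.09 for Creld2 and 0.45 ± 0.06 for Dnajb11. ER chaperones had adjusted p = 2.95e-05 by camera and adjusted p = 0.213 with an estimated correlation. In the hypoxia response 6 of 23 members rose, 2 fell and 15 did not pass (9 and 2 adjusted over the list alone). Log2 changes were 0.50 ± 0.10 for Pdk1 and 1.13 ± 0.20 for Pfkfb3. Hypoxia response genes had adjusted p = 0.0174 by camera and adjusted p = 0.213 with an estimated correlation. For oxidative stress and metallothionein 4 of 24 members rose, 1 fell and 19 did not pass (6 and 1 adjusted over the list alone, 9 and 2 with the replicate block). The log2 change was 0.67 ± 0.14 for Slc7a11. The oxidative stress list had adjusted p = 0.0245 by camera and adjusted p = 0.526 with an estimated correlation. This call ended without 2 mmol/l replicate 1 (0.0572), 2 mmol/l replicate 4 (0.0545), 5 mmol/l replicate 3 (0.101), 10 mmol/l replicate 3 (0.0720) or 30 mmol/l replicate 2 (0.116), each as an adjusted p. Insulin granule genes had a lower mean over the ends, with -0.23 ± 0.05 for Scg5. Here 0 of 16 members rose, 3 fell and 13 did not pass (0 and 9 adjusted over the list alone, 0 and 10 with the replicate block). Insulin granule genes had adjusted p = 4.74e-05 by camera and adjusted p = 0.262 with an estimated correlation. Cytosolic ribosomal proteins did so too, with -0.20 ± 0.04 for Rpl19. Here 0 of 20 members rose, 3 fell and 17 did not pass (0 and 6 adjusted over the list alone, 0 and 13 with the replicate block). Ribosomal proteins had adjusted p = 4.74e-05 by camera and adjusted p = 0.494 with an estimated correlation. Quantile normalization ended the calls of both lists (adjusted p = 0.0804 and 0.542), of Scg5 (-0.06, adjusted p = 0.193) and of Rpl19 (-0.07, adjusted p = 0.2). With the replicate block, the heat shock list passed upward (adjusted p = 0.0308) and fatty acid oxidation (0.0308), delta cell (0.0363) and stellate cell markers (0.0109) passed downward, against adjusted p of 0.0879, 0.0638, 0.159 and 0.387 without it. An estimated correlation beside the block ended these 4 calls (adjusted p = 0.399, 0.325, 0.196 and 0.399). For p53 targets the median was -0.01, the mean 0.04, and for duct cell markers -0.05 and 0.01, with adjusted p of 0.615 and 0.802.

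By limma 1425 probe sets differed between the ends and the middle, 627 higher and 798 lower at the ends, and 3103 with the replicate block, 1336 higher and 1767 lower. The contrast mixes a change at low glucose with one at high glucose, and a large change at 1 end alone can pass it.

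**Figure D3:**
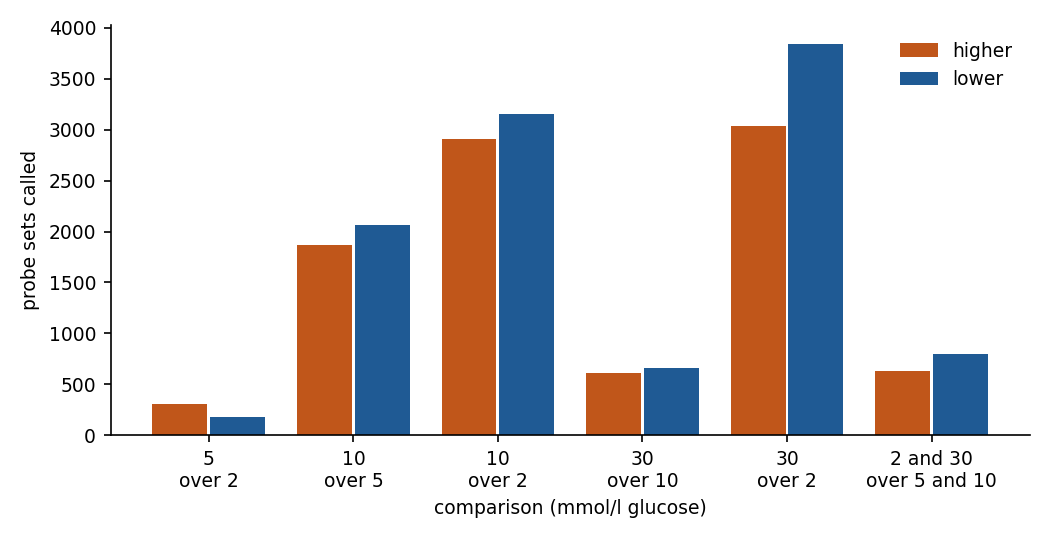
Number of probe sets (vertical axis, from 0) called higher (orange) and lower (blue) in each comparison of 4 against 4 arrays, and of 2 and 30 against 5 and 10 mmol/l. The most were called at 30 against 2 mmol/l, with 3031 higher and 3838 lower, and the fewest at 5 against 2 mmol/l, with 310 and 175.

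Signs of array quality were compared between concentrations by exact permutation tests (two-sided, 70 assignments, smallest possible p 0.0286). The Actb 3 prime to 5 prime ratio was 1.76 ± 0.131 at 2 mmol/l and 2.04 ± 0.0835, 2.07 ± 0.136 and 2.04 ± 0.0850 at 5, 10 and 30 mmol/l (SD, n = 4). Each of these 3 differences had an exact permutation p of 0.0286 and an adjusted p of 0.0571 over 6 pairs of groups, so they did not pass, and the ratio was lower at 2 mmol/l in 4 of 4 replicate numbers each time. For Gapdh the ratio was 0.864 ± 0.0676, 0.825 ± 0.0621, 0.798 ± 0.0585 and 0.898 ± 0.0515 at 2, 5, 10 and 30 mmol/l (SD, n = 4). The largest difference, 30 against 10 mmol/l, had an exact permutation p of 0.0857 and an adjusted p of 0.4. In 5 of 6 pairs of groups 4 of 4 replicate numbers differed in the same direction.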

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

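The tests against RNA of another cell type were chosen only after the results were seen. In 35 of 644 groups of 4 arrays (155 named genes and 6 array measures), 1 array lay far from the other 3, and chance flags about 1 in 20 groups. Values are log2 signals, with the range of the other 3 arrays in parentheses. At 2 mmol/l these were Acvr1c 5.73 in replicate 1 (6.73 to 6.89), Bbc3 7.37 in replicate 4 (7.74 to 7.81), Luc7l 7.78 in replicate 3 (8.18 to 8.22), Psat1 8.93 in replicate 3 (9.31 to 9.38), Sec61b 11.34 in replicate 3 (11.49 to 11.51) and Tmem80 6.12 in replicate 2 (6.59 to 6.67). At 5 mmol/l these were Adhfe1 7.44 in replicate 2 (6.92 to 6.98), Atp5f1b 11.46 in replicate 4 (11.42 to 11.43), Ccdc113 4.97 in replicate 2 (5.55 to 5.62), Cry1 7.49 in replicate 3 (8.14 to 8.20), Gem 6.20 in replicate 3 (6.65 to 6.69), Insrr 6.45 in replicate 2 (6.0 to 6.06), Klf15 8.39 in replicate 4 (7.49 to 7.51), LOC100909675 6.38 in replicate 1 (7.51 to 7.60) and Psat1 8.97 in replicate 4 (8.81 to 8.83). At 10 mmol/l these were Ddit3 9.26 in replicate 4 (7.63 to 7.82), G0s2 8.04 in replicate 1 (7.02 to 7.16), Lrrc39 6.47 in replicate 3 (6.84 to 6.86), Pgk1 10.99 in replicate 4 (10.70 to 10.73), Ppp1r15a 8.41 in replicate 4 (7.79 to 7.87), Srxn1 8.78 in replicate 1 (7.78 to 7.94) and Tmem80 7.72 in replicate 4 (7.22 to 7.30). At 30 mmol/l these were Atf5 10.02 in replicate 2 (10.28 to 10.33), Ddit3 8.94 in replicate 4 (7.92 to 8.03), Ins2 12.92 in replicate 2 (12.57 to 12.59), Ivd 8.10 in replicate 1 (7.70 to 7.75), Lrrc39 5.95 in replicate 4 (5.30 to 5.36), Mmp13 7.08 in replicate 1 (7.69 to 7.81), Psma5 10.33 in replicate 1 (10.18 to 10.19), Psmd14 10.06 in replicate 3 (9.93 to 9.94), Rasgrf1 5.20 in replicate 4 (6.27 to 6.43), Scg3 12.56 in replicate 1 (12.79 to 12.83) and Sst 13.05 in replicate 2 (12.88 to 12.90). Of the array measures, the percentage of probe sets at the floor was 11.6 at 2 mmol/l in replicate 1 (9.79 to 10.0) and the Actb 3 prime to 5 prime ratio was 2.16 at 5 mmol/l in replicate 3 (1.98 to 2.01).

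The hormones Ins1, Ins2, Iapp, Gcg and Sst were higher at 10 than at 2 mmol/l by a mean of 0.55, while the hybridization controls, which carry no islet RNA, were higher by 0.51. Among the 200 next brightest probe sets, 82.5% had a smaller change than the hormones' median of 0.56, with a median of 0.38 and a 95th percentile of 0.68, so a rise common to bright signals may account for the hormones. Within groups the hormones followed the controls with a slope of 0.33 (95% interval -0.30 to 0.96). The upper end over the ratio of changes (1.07) was 0.897, and the 4 arrays per group leave this slope imprecise. Array brightness and a rise of hormone transcripts with glucose cannot be told apart here, and a biological effect of glucose stays open.

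Hypoxia response genes, among them Pdk1 and Adm, were higher at 30 than at 10 mmol/l (median 0.40). Members shared with glycolysis and carbohydrate response element lists do not account for it: without those 4 members, 5 of 19 rose and 0 fell, with a median of 0.39 and an adjusted p of 6.01e-05 (0.0370 with an estimated correlation). Lists of alpha, delta, endothelial or stellate cells had a median plus SD of at most 0.0885. This SD is between members, not arrays, so RNA of these cells stays open. RNA of duct cells or leukocytes stays open, with members that go both ways and a median plus SD of up to 0.487. RNA of acinar, PP, epsilon, Schwann or neural cells stays open, since these lists have 1 to 3 tested genes each and the highest median among them was 0.927, from the acinar marker Bhlha15 alone. Use of oxygen and effects of glucose itself were not tested and stay open.

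Integrated stress response genes such as Trib3 and p53 targets such as Mdm2 were lower at 10 than at 5 mmol/l. Quantile normalization, which kept both calls (highest adjusted p = 0.00123), argues against the authors' scaling. Median centring (0.00208) moves all genes alike and is no test. With an estimated correlation neither list was called (adjusted p = 0.0563 and 0.0504). The Actb 3 prime to 5 prime ratio was higher at 10 than at 5 mmol/l in 2 of 4 replicate numbers (exact permutation p = 0.657), which leaves RNA quality open. Effects of glucose and of islet survival were not tested and stay open.

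For pairs of concentrations, the real split alone (1 of 35 splits of 8 arrays) gave its count. It was 485 at 5 over 2 mmol/l against at most 0 in the other splits and 3935 at 10 over 5 mmol/l against 1. It was 6064 at 10 over 2 against 1, 1271 at 30 over 10 against 1 and 6869 at 30 over 2 mmol/l against 0. These splits ignore the pairing by number, so they cannot exclude chance. Among the 8 splits that part all 4 pairs of the same number, the others differ in which preparations change sides, and none passed limma, but 8 splits are too few for a share under 1 in 20. For the 4 concentrations 1 of 100 splits, the real one, reached 7785, and the highest other was 1049. These also ignore the pairing and cannot exclude chance. For the ends over the middle, 2 of 100 splits that ignore pairing reached the real 1425. Chance is not excluded, as the highest other gave 2302. That split set 7 of its 8 arrays on 1 side at 10 or 30 mmol/l and 1 at 2 or 5 mmol/l, and so followed the larger difference between these concentrations.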

How the results depend on the processing

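The joint use of the replicate block with an estimated correlation, and median centring of lists, were tests chosen only after the results were seen. Of 235 named calls, of which 228 or more had a value under each setting given, quantile normalization ended 11 and reversed 1 (Gcg at 10 over 2 mmol/l, -0.063), median centring ended 7, no level filter 15, no trend 13, the mean of probe sets 5 and log2(value + 50) 2, while both blocks, robust eBayes and no floor ended 0. Leaving out 1 array ended 3 to 14, and 1 replicate number 21 to 44. Of 62 list calls, quantile normalization ended 12 and reversed 2 (cytosolic ribosomal proteins, medians -0.041 at 10 over 2 and -0.079 at 30 over 2 mmol/l), and an estimated correlation ended 53. It left 0, 0, 0, 4, 4 and 1 lists called at 5 over 2, 10 over 5, 10 over 2, 30 over 10, 30 over 2 mmol/l and the ends over the middle, and 0, 0, 0, 4, 1 and 0 with the replicate block too; in camera at an unadjusted p under 0.05 these were 5, 8, 7, 7, 9 and 6 and 5, 7, 6, 7, 9 and 6. Numbers of probe sets at 5 over 2, 30 over 10 and ends over middle were 1839, 2754 and 3103 with the replicate block, 1587, 2486 and 2756 with a random block and 1254, 2081 and 2330 with a scan-day block, and 1490 had another order of means with the replicate block. At 5 over 2 mmol/l median centring gave 298 and no trend 180. At an adjusted p under 0.01 the counts were 75, 2246, 3916 and 485 (5 over 2, 10 over 5, 10 over 2, 30 over 10 mmol/l) and 521 (ends over middle), and at 1.5-fold 124, 1742, 3013, 509, 3663 (30 over 2 mmol/l) and 163, with 4839 over the 4 concentrations, of which 662 rose, 1230 fell then rose, 1363 rose then fell and 483 had another order; these thresholds lower counts by construction. With only the groups compared, which leaves fewer arrays, 5 over 2 gave 104 and 30 over 10 mmol/l 817, and this setting gives no separate value for the contrasts that use all 4 groups. Without 1 array or 1 replicate number, the counts ranged from 25 to 475 (5 over 2), 2508 to 3926 (10 over 5), 384 to 1284 (30 over 10 mmol/l), 440 to 1445 (ends over middle) and 551 to 739 (another order). For the changes with blocks, scaling, trend and correlation, the cause was not tested.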

Other observations

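The tests of 3 gene lists here, adjusted over these 3 alone, and the named genes were chosen only after the results were seen. Clock genes were lower at 10 than at 2 mmol/l, with -3.16 ± 0.19 for Dbp, -1.53 ± 0.14 for Hlf, -1.39 ± 0.19 for Nfil3, -1.0 ± 0.16 for Cry1 and -0.87 ± 0.08 for Per2 (log2 ± SE, n = 4 per group). In this list 0 of 16 members rose, 12 fell and 4 did not pass (0 and 12 adjusted over the list alone). Clock genes had adjusted p = 9.15e-07 by camera and adjusted p = 0.0109 with an estimated correlation. Without the members whose change had prompted the list, 12 members gave adjusted p = 7.60e-04 by camera and adjusted p = 0.0235 with an estimated correlation.

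From 10 to 30 mmol/l, genes of branched-chain and other amino acid breakdown were lower, with -0.85 ± 0.11 for Aldh6a1, -0.54 ± 0.10 for Ivd and -0.72 ± 0.14 for Aass. In this list 2 of 25 members rose, 13 fell and 10 did not pass (3 and 15 adjusted over the list alone). Amino acid breakdown had adjusted p = 1.07e-05 by camera and adjusted p = 9.27e-04 with an estimated correlation. Without Dhtkd1 and Adhfe1, whose change had prompted the list, 23 members gave adjusted p = 9.18e-04 by camera and adjusted p = 0.00780 with an estimated correlation. The kinase that switches off branched-chain ketoacid breakdown, Bckdk, rose by 0.59 ± 0.14. Proteasome subunits were higher at 30 than at 10 mmol/l, with 0.48 ± 0.09 for Psmd14 and 0.41 ± 0.09 for Psma5. Here 12 of 30 members rose, 0 fell and 18 did not pass (23 and 0 adjusted over the list alone, 21 and 0 with the replicate block). Proteasome subunits had adjusted p = 2.42e-15 by camera and adjusted p = 0.00845 with an estimated correlation. At 30 against 2 mmol/l 20 of 30 members rose, 1 fell and 9 did not pass (20 and 1 adjusted over the list alone). Proteasome subunits had adjusted p = 7.04e-08 by camera and adjusted p = 0.0380 with an estimated correlation. Beside the other 2 lists without the members that had prompted them, this call ended with an estimated correlation (adjusted p = 0.0570).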
